A study of Mus musculus with 167 samples.

How the data were processed

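The starting point was the processed tables that the authors deposited, all in FPKM (fragments counted relative to transcript length and to all mapped fragments). By the submitters' processing notes, the sorted-cell RNA was taken up in Trizol and made into TruSeq libraries, and reads were called with CASAVA 1.8.2, aligned to mm9 with TopHat2 2.0.9 and Bowtie2 2.1.0, and quantified with Cufflinks 2.1.1 and Cuffdiff. For the Ter119+ libraries and the single cells the submitters' processing notes name the same kinds of tool without versions. The single cells were captured on the Fluidigm C1 and prepared with Nextera XT. Raw reads were not analysed here. The units in each table fit the values in it, and no value column was left without a sample.

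The sorted-cell table held 18454 rows. Symbols that occurred more than once (31 symbols, 62 rows) were left out, since their rows could not be told apart, which left 18392. Genes with at least 1 FPKM in at least 2 libraries were tested: 14199 in the sorted-cell table and 11448 of 14317 in the Ter119+ table. The single-cell table held 23235 rows, of which 6276 were at 0 in every cell. Every cell had at least 1000 genes at 1 FPKM or more, so none was removed. No doublet caller was run. Positions are given for Ter119+ genes only, as mm9 coordinates from the deposited table, because the other tables carry none.

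Values were taken as log2(FPKM + 1) and fitted with limma 3.58.1 in R 4.3.3, with 1 mean per gate and stage and an intensity trend in the moderated variance. The fit of the sorted-cell table had 9 residual degrees of freedom, and 2 in the Ter119+ table. Each comparison of gates averaged E10.5 and E12.5, each comparison of stages averaged the 2 CD45- PS34 gates or the CD45+ PS34 and HSPC gates, and the difference of a contrast between stages was tested as an interaction term. P-values were two-sided and adjusted by Benjamini and Hochberg over all genes tested, and a gene was called at an adjusted p below 0.05. Fold changes are log2 with their SE. Means and SDs of FPKM are over the libraries of a side, with stages pooled.

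Before the data were examined, 25 gene lists were fixed: sorting gate, conversion factors, endothelial, arterial and Notch, venous, stem cell regulators, stem cell surface, fetal program, Hoxa, granulocyte-monocyte progenitor, macrophage, megakaryocyte, mast and basophil, erythroid, heme synthesis, embryonic globin, adult globin, globin switching, lymphoid, trophoblast, mesenchyme, endoderm, interferon and inflammation, cell cycle, and stress. Lists with at least 3 tested genes were compared with all other genes by limma's camera with a preset correlation of 0.01 and again with an estimated correlation. List p-values were adjusted over the lists of a comparison. Each list also has a count of genes adjusted over the list alone.

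The rule for named genes was also fixed before the data were examined. It takes the 5 gate genes and 4 conversion factors, the 6 called genes with the largest fold change in each direction, and from each list the 2 called members with the largest fold change (where none was called, the member with the highest mean). Those taken by fold change had a mean of at least 10 FPKM in the higher group and every library of 1 side above every library of the other within each stage, or within each gate for the stage comparisons. Symbols that only number a gene model, and small RNAs, were passed over. Of the genes the rule takes, the text gives mainly those whose call stood in each alternative and without each single library. Other list members were named after their values were seen. In single cells the rule takes the gate genes, the factors, the member of each list found in most cells, and the genes with the largest mean log2 difference between groups.

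In single cells a gene counted as found at 1 FPKM or more. Shares have exact Clopper-Pearson 95% intervals, which reach 7.4% for a count of 0 of 48 cells. Tables and figures were made in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. The fit was tested on simulated data with 1 spread per gene. In these, 100 genes were changed by a log2 change of 1 and 100 by 2, alternately up and down. They had a mean log2(FPKM + 1) above 3, so recovery nearer the floor was not measured. Unequal spread of gates was not tested. Among genes changed by 2 the fit found 94 to 99 in the sorted-cell comparisons and 78 in the Ter119+ comparison, with 8 to 15 false calls. Among genes changed by 1 it found 54 to 71, and 18 in the Ter119+ comparison.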

Results

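The data describe RNA from cells sorted by flow cytometry from wild-type C57BL/6 mouse placenta at embryonic stages E10.5 and E12.5, in a study of the precursors that give rise to blood. PS34 is the submitters' name for cells positive for Prom1 (CD133), Sca1 (the product of Ly6a) and CD34. The first set holds 19 bulk libraries from 5 gates at each of 2 stages. These gates are CD45- cKit- PS34 (3 libraries at E10.5 and 2 at E12.5), CD45- cKit+ PS34 (2 and 2), CD45+ PS34 (which the labels also give as cKit+; 2 and 2), HSPC (CD45+ CD34+ cKit+; 2 and 2) and MBC (CD45+ CD34- cKit-; 1 and 1). The labels do not spell out MBC. The second set holds 4 libraries of Ter119+ cells, 2 grown from E12.5 PS34 cells and 2 from E12.5 HSPC, after 4 days on OP9 stroma and 14 days in methylcellulose. The third set holds 144 single cells, 48 each of E10.5 CD45- PS34, E12.5 CD45- PS34 and E12.5 HSPC.

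All values are FPKM as deposited, so the number of reads behind a value is unknown. The 19 bulk libraries had 10654 to 12027 genes at 1 FPKM or more, and their FPKM sums ran from 444035 to 746306. The CD45- cKit+ libraries listed 2894 to 3541 genes at exactly 0 and the CD45+ PS34 libraries 4925 to 6059. A value of exactly 0 can be a failed estimate: Flt1, an endothelial receptor, was listed at 0 in every sorted bulk library but reached 1 FPKM in 44 of 48 E10.5 single cells. The Ter119+ libraries had 10676 to 11383 genes at 1 FPKM or more. Single cells had 2378 to 7914, with group medians of 5192.5 (E10.5 PS34), 4278.5 (E12.5 PS34) and 4527.5 (E12.5 HSPC). Replicate libraries of a sorted gate correlated at r = 0.887 to 0.981 across genes, which are not independent replicates. No label says that libraries came from separate animals, so the p-values measure the spread between these samples, which may be technical. The sorted-cell and single-cell tables were each normalized by the submitters on their own, so levels are compared within a table only, unless stated.

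The first comparison asked how CD45- PS34 cells with and without cKit, the receptor for stem cell factor, differ over both stages. Kit RNA was higher in the cKit+ gate by a log2 fold change of 2.09 ± 0.28 (SE), at 52.1 ± 4.22 FPKM (SD, n = 4) against 12.6 ± 5.85 (n = 5; adjusted p = 0.000433). Prom1 was lower in it by 1.84 ± 0.26, at 21.7 ± 4.7 against 82.2 ± 28.1 FPKM (adjusted p = 0.00067). Arterial and Notch genes were lower in the cKit+ gate, where 7 of the 14 tested fell, 0 rose and 7 were not called. Among them, the arterial kinase gene Bmx fell by 1.96 ± 0.38 (3.07 ± 1.2 against 14.4 ± 5.9 FPKM, adjusted p = 0.00486) and the arterial connexin gene Gja5 by 1.78 ± 0.35 (31.9 ± 16.4 against 118 ± 98.7 FPKM, adjusted p = 0.0063). The count adjusted over the list alone was 9 lower, and the list test gave adjusted p = 7.73e-07, or adjusted p = 0.127 with an estimated correlation. Averaged over the 2 stages, pan-endothelial genes did not move as a list: 1 of 17 rose, 3 fell and 13 were not called (adjusted p = 0.826; 1 rose and 4 fell adjusted over the list alone). This average hides a change with stage, since the difference between the gates fell from E10.5 to E12.5 by a median of 0.84 over the endothelial genes (adjusted p = 2.52e-09, or adjusted p = 0.143 with an estimated correlation) and 1.42 over the arterial genes (adjusted p = 7.41e-12, or adjusted p = 0.0443 with an estimated correlation). Kdr rose by 1.00, and Clec14a (-0.78), Sox17 (-0.74) and Sox7 (-0.59) fell. Sox17 kept its call without any single library. Kdr lost it without E10.5 cKit+ library 1, E12.5 cKit- library 1 or either E12.5 cKit+ library, Clec14a without any CD45- or HSPC library except E10.5 cKit- library 3, and Sox7 without any CD45- library except E10.5 cKit- library 2 or without either E12.5 HSPC library.

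Of the genes that the named-gene rule takes by fold change, Guca2b, which encodes uroguanylin, fell the most in the cKit+ gate, by 7.11 ± 0.96 (2.81 ± 1.95 against 617 ± 454 FPKM, adjusted p = 0.000478). Prap1, a secreted protein of gut and uterine epithelium, fell by 5.56 ± 0.98 (180 ± 84.7 against 10160 ± 6290 FPKM, adjusted p = 0.00293). Klk1, Aqp8, Napsa and Spp1 fell by 5.12 to 6.15. In the other direction, Scgb1a1, the secretoglobin of airway club cells, rose by 6.08 ± 0.51 (104 ± 42.1 against 0.707 ± 1.58 FPKM, adjusted p = 1.8e-05). Rarres2, which encodes chemerin, rose by 3.39 ± 0.38 (264 ± 53 against 31 ± 20.1 FPKM, adjusted p = 0.000137). Igf2bp1, a fetal RNA-binding protein gene, rose by 3.22 ± 0.47 (100 ± 82.7 against 6.07 ± 2.88 FPKM, adjusted p = 0.000754). Markers of other placental cells moved both ways: Cdh1, the epithelial cadherin gene, fell by 2.76 ± 0.38 and Epcam by 2.50, while the stromal genes Dcn and Des rose by 4.04 ± 0.72 and 2.35 ± 0.31. Of 17 trophoblast genes 2 rose (Hand1 and Elf5) and 3 fell (Cdh1, Epcam and Krt7; 5 and 3 adjusted over the list alone, adjusted p = 0.829), with a median log2 fold change of -0.073 and a mean of 0.053. Hand1 lost its call without either E10.5 cKit+ library, either E12.5 cKit+ library or E12.5 cKit- library 2, and Elf5 without library 2 of E10.5 cKit+, E12.5 cKit+ or E12.5 cKit-. Of 16 mesenchyme genes 3 rose (Dcn, Des and Pdgfra) and 1 fell (Tagln; 4 and 2 adjusted over the list alone, adjusted p = 0.826), with a median of -0.355 and a mean of 0.159. Pdgfra lost its call without E10.5 cKit+ library 1, E12.5 cKit- library 1 or either E12.5 cKit+ library, and Tagln without any cKit+ library or E12.5 cKit- library 2.

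Immediate-early stress genes were lower in the cKit+ gate: Nr4a1 (-0.75), Ier2 (-0.58), Egr1 (-0.56) and Dusp1 (-0.44) fell out of 16 tested, 0 rose and 12 were not called. The list gave 10 lower adjusted over the list alone and adjusted p = 4.17e-05, or adjusted p = 0.423 with an estimated correlation. None of these 4 falls reached a log2 change of 1, and without either E10.5 CD45+ PS34 library, which enters through the shared spread, 8 members fell. Of 19 interferon and inflammatory genes, 8 fell and 0 rose (1 rose and 10 fell adjusted over the list alone, adjusted p = 0.000136, or adjusted p = 0.258 with an estimated correlation), among them Isg15 (-0.96 ± 0.13). That count was 4 without E10.5 cKit+ library 1 or E12.5 cKit+ library 2, and 5 without E10.5 cKit+ library 2, E12.5 cKit+ library 1 or either E12.5 cKit- library. Of 20 cell-cycle genes 1 rose (Rrm2 by 1.07) and 0 fell (5 rose adjusted over the list alone, adjusted p = 3.25e-05, or adjusted p = 0.127 with an estimated correlation). Rrm2 lost its call without any cKit+ library, E10.5 cKit- library 1, either E12.5 cKit- library or any HSPC library, and the count was 2 without E10.5 cKit- library 2 or 3 and 3 without either E10.5 CD45+ PS34 library. The conversion factors Gata2 (0.38; adjusted p = 0.573) and Etv6 (-0.27; adjusted p = 0.213) were not called. In all, 1467 of 14199 genes were called, 451 higher and 1016 lower in the cKit+ gate (30.7% higher). Under quantile normalization the split was 674 higher and 918 lower (42.3% higher). The count was 827 without E10.5 cKit+ library 1, and 936 and 843 without E12.5 cKit+ libraries 1 and 2.

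The second comparison set CD45+ PS34 cells against CD45- cKit+ PS34 cells, the step at which the pan-leukocyte antigen CD45 appears. Ptprc, which encodes CD45, was higher by 5.47 ± 0.48 (55.2 ± 13.8 against 0.255 ± 0.198 FPKM, n = 4 each; adjusted p = 4.78e-06). All 18 macrophage genes rose with it, among them the lysozyme gene Lyz2 by 7.92 ± 0.72 (1963 ± 786 against 7.63 ± 4.49 FPKM, adjusted p = 6e-06) and the cathepsin gene Ctss by 7.92 ± 0.67 (740 ± 322 against 2.18 ± 1.56 FPKM, adjusted p = 3.58e-06). The same 18 rose adjusted over the list alone, and the list test gave adjusted p = 2.7e-25. Gp49a, the neutrophil gene S100a9, the class II chaperone gene Cd74 and the cytokine gene Il1b rose by 7.66 to 8.01. Of 12 granulocyte-monocyte progenitor genes 5 rose and 0 fell (5 adjusted over the list alone, adjusted p = 0.000342): Ly6c2 (7.11), Hp (4.32), Csf3r (4.19), Clec12a (3.77) and Cebpa (2.20). Of 19 interferon and inflammatory genes 12 rose and 0 fell (13 adjusted over the list alone, adjusted p = 8.44e-09), with Ifitm1 up by 4.39 ± 0.74 and Tnfrsf1b by 3.26 ± 0.22. These are averages over 2 stages, and the interferon difference grew from E10.5 to E12.5 by a median of 0.97 (adjusted p = 6.69e-07, or adjusted p = 0.215 with an estimated correlation).

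Runx1, the transcription factor needed for blood to form from endothelium, rose by 2.53 ± 0.36 (36.6 ± 27.4 against 4.93 ± 2.58 FPKM, adjusted p = 0.000335). The lymphoid and stem cell regulator Ikzf1 rose by 2.68 ± 0.34 (6.93 ± 3.65 against 0.156 ± 0.154 FPKM, adjusted p = 0.000108). Of 12 stem cell surface genes 6 rose, including Cd48 (4.42 ± 0.46) and Itga4 (2.43), and 0 fell (7 rose and 1 fell adjusted over the list alone). That list gave adjusted p = 0.00182, or adjusted p = 0.174 with an estimated correlation. Of 20 regulator genes, 4 rose (Ikzf1, Runx1, Cbfa2t3 by 0.80 and Etv6) and 0 fell (4 adjusted over the list alone, adjusted p = 0.385), and Cbfa2t3 lost its call without E10.5 cKit+ library 1. Etv6, a conversion factor, rose by 0.60 ± 0.13 (23.8 ± 7.34 against 15.3 ± 4.27 FPKM, adjusted p = 0.00577) and Ly6a by 0.90 ± 0.20, both below a log2 change of 1. Gata2 (-0.44; adjusted p = 0.422) and Kit (-0.39; adjusted p = 0.413) were not called.

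Endothelial and proliferation genes were lower in the CD45+ PS34 gate. Of 17 endothelial genes 8 fell and 0 rose (11 adjusted over the list alone, adjusted p = 2.02e-05, or adjusted p = 0.18 with an estimated correlation). The falls were small: the claudin gene Cldn5 fell by 0.73 ± 0.14 and the junction gene Cdh5 by 0.55. They also changed with stage, as the list's difference rose from E10.5 to E12.5 by a median of 0.72 (adjusted p = 0.000216, or adjusted p = 0.431 with an estimated correlation). Among the 20 cell-cycle genes, 14 fell and 0 rose (17 adjusted over the list alone, adjusted p = 1.13e-07), as did 7 of 12 fetal-program genes (8 adjusted over the list alone, adjusted p = 0.000162, or adjusted p = 0.177 with an estimated correlation). Igf2bp1 fell by 2.96 ± 0.49 (adjusted p = 0.000966) and the imprinted RNA H19 by 1.28 ± 0.14 (1042 ± 646 against 2928 ± 2310 FPKM, adjusted p = 3.38e-05). The placental keratins Krt18 and Krt19 fell by 1.51 ± 0.31 and 1.39 ± 0.30. The uterine keratinization gene Sprr2f fell by 5.07 ± 0.47 to 0.179 FPKM. Several of these counts leaned on single libraries. The cell-cycle count was 8 without E10.5 cKit+ library 1 and 9 without E12.5 cKit+ library 1. The fetal-program count was 3 without E10.5 cKit+ library 1, and 4 without E10.5 CD45+ PS34 library 2 or E12.5 cKit+ library 1. The endothelial count was 3 without E12.5 cKit+ library 1, 4 without either E10.5 cKit+ library or E10.5 CD45+ PS34 library 2, and 5 without E12.5 cKit+ library 2, E12.5 CD45+ PS34 library 1 or either E12.5 HSPC library. In all, 2480 genes were called, 1488 higher and 992 lower (60% higher), against 1370 higher and 1530 lower under quantile normalization (47.2% higher). The total was 1566 without E12.5 cKit+ library 2.

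The third comparison set HSPC, gated as CD45+ CD34+ cKit+, against CD45- cKit+ PS34 cells. The granule enzyme gene Mpo was at 145 ± 128 FPKM in HSPC and 0.099 ± 0.0812 in the CD45- gate (log2 fold change 6.55 ± 0.23, n = 4 each; adjusted p = 1.3e-08). Of 12 granulocyte-monocyte progenitor genes 11 rose and 0 fell (11 adjusted over the list alone, adjusted p = 1.27e-15). All 18 macrophage genes rose here as well (18 adjusted over the list alone, adjusted p = 1.93e-26), with Ctss up by 7.98 ± 0.67, Lyz2 by 7.84 ± 0.72 and the complement gene C1qb by 7.15 ± 0.64 (188 ± 71.1 against 0.292 ± 0.37 FPKM). Ccl6 and Tyrobp rose by 7.91 ± 0.84 and 7.13 ± 0.94. Of 7 mast and basophil genes 4 rose and 0 fell (4 adjusted over the list alone): Cpa3, a mast cell protease, by 4.10 ± 0.46 (64.4 ± 78 against 0.0217 ± 0.0435 FPKM, adjusted p = 4.6e-05), Hdc by 4.03 ± 0.36, Gzmb by 2.80 and Ms4a2 by 1.26. That list gave adjusted p = 0.00144, or adjusted p = 0.131 with an estimated correlation.

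Of 12 stem cell surface genes 7 rose and 1 fell (7 and 1 adjusted over the list alone, adjusted p = 0.000175, or adjusted p = 0.105 with an estimated correlation). Ptprc rose by 4.89 ± 0.48 and Cd48 by 4.08 ± 0.46, while Procr, the stem cell and endothelial protein C receptor gene, fell by 0.77. Procr lost its call without any library of the CD45- cKit+ gate, either E12.5 HSPC library or E10.5 HSPC library 2. Ikzf1 rose by 3.26 ± 0.34 (12.8 ± 9.7 FPKM in HSPC; adjusted p = 2.43e-05) and Myb, needed for definitive blood stem cells, by 2.21 ± 0.37 (9.24 ± 6.62 against 0.948 ± 0.694 FPKM, adjusted p = 0.00119). Runx1 rose by 2.03 and Etv6 by 0.74 ± 0.13, the latter below a log2 change of 1. Over the 20 regulator genes 5 rose (Ikzf1, Myb, Runx1, Gfi1b and Etv6) and 1 fell (Mecom by 0.99; 6 and 2 adjusted over the list alone), with adjusted p = 0.112. Mecom lost its call without E10.5 cKit+ library 2, E12.5 cKit+ library 1 or library 1 of either HSPC stage. Gfi1b, a conversion factor, rose by 1.57 and lost its call without library 1 of E10.5 cKit+, E10.5 HSPC or E12.5 HSPC, or without E12.5 cKit+ library 2. Of 5 globin-switching genes 4 rose and 0 fell (Myb, Bcl11a by 1.51, Lin28b by 1.12 and Zbtb7a by 0.60; 4 adjusted over the list alone, adjusted p = 0.00562, or adjusted p = 0.131 with an estimated correlation). That count was 2 without E10.5 cKit+ library 2; Bcl11a also lost its call without E12.5 HSPC library 1, and Zbtb7a without any library of these 2 gates except E12.5 HSPC library 1. Of 19 interferon and inflammatory genes 8 rose and 0 fell (9 adjusted over the list alone, adjusted p = 0.000149, or adjusted p = 0.131 with an estimated correlation), with Ifitm1 up by 4.51 ± 0.74 and Tnfrsf1b by 2.79 ± 0.22. It was 5 without E10.5 cKit+ library 1, E12.5 cKit+ library 2 or E12.5 HSPC library 2.

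Prom1, in contrast, fell in HSPC by 1.39 ± 0.27 (7.93 ± 2.96 against 21.7 ± 4.7 FPKM, adjusted p = 0.00342). Of 17 trophoblast genes 7 fell and 0 rose (11 adjusted over the list alone, adjusted p = 6.26e-07), among them the keratin genes Krt7 (-2.59 ± 0.35; 15.3 ± 11.9 against 95.6 ± 59.7 FPKM) and Krt19 (-2.52). Of 17 endothelial genes 9 fell and 0 rose (10 adjusted over the list alone, adjusted p = 5.3e-06, or adjusted p = 0.138 with an estimated correlation). Esam, an endothelial adhesion gene, fell by 0.97 ± 0.15 yet stayed at 176 ± 50.5 FPKM in HSPC, against 345 ± 106. That count was 4 without E10.5 cKit+ library 2, E12.5 cKit+ library 1 or E12.5 HSPC library 2, and 5 without either E10.5 HSPC library or E12.5 cKit+ library 2. Of 16 stress genes 4 fell and 0 rose (Btg2 by 0.91, Klf6 by 0.65, Egr1 by 0.45 and Jun by 0.36; 7 adjusted over the list alone, adjusted p = 0.000213, or adjusted p = 0.3 with an estimated correlation). None reached a log2 change of 1. Jun lost its call without any library other than the 3 E10.5 cKit- libraries, E10.5 HSPC library 1 and the MBC libraries. Of 14 arterial genes 1 rose (Cxcr4 by 1.84) and 2 fell (Gja5 by 1.57 and Unc5b by 0.59; 1 and 6 adjusted over the list alone, adjusted p = 0.00266, or adjusted p = 0.217 with an estimated correlation). Gja5 lost its call without E10.5 cKit+ library 2 or library 1 of either HSPC stage, and Unc5b without any library of these 2 gates except E12.5 HSPC library 2. The arterial count of falls was 5 without either E10.5 CD45+ PS34 library and 4 without E10.5 cKit- library 1 or 2. F3, the tissue factor gene, fell by 3.33 ± 0.42, and Lcn2 by 3.23 ± 0.54. Cd34 (-0.27; adjusted p = 0.313) and Kit (0.28; adjusted p = 0.654) were not called. In all, 2129 genes were called, 1363 higher and 766 lower (64% higher), against 1265 higher and 1085 lower under quantile normalization (53.8% higher).

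**Figure D1:**
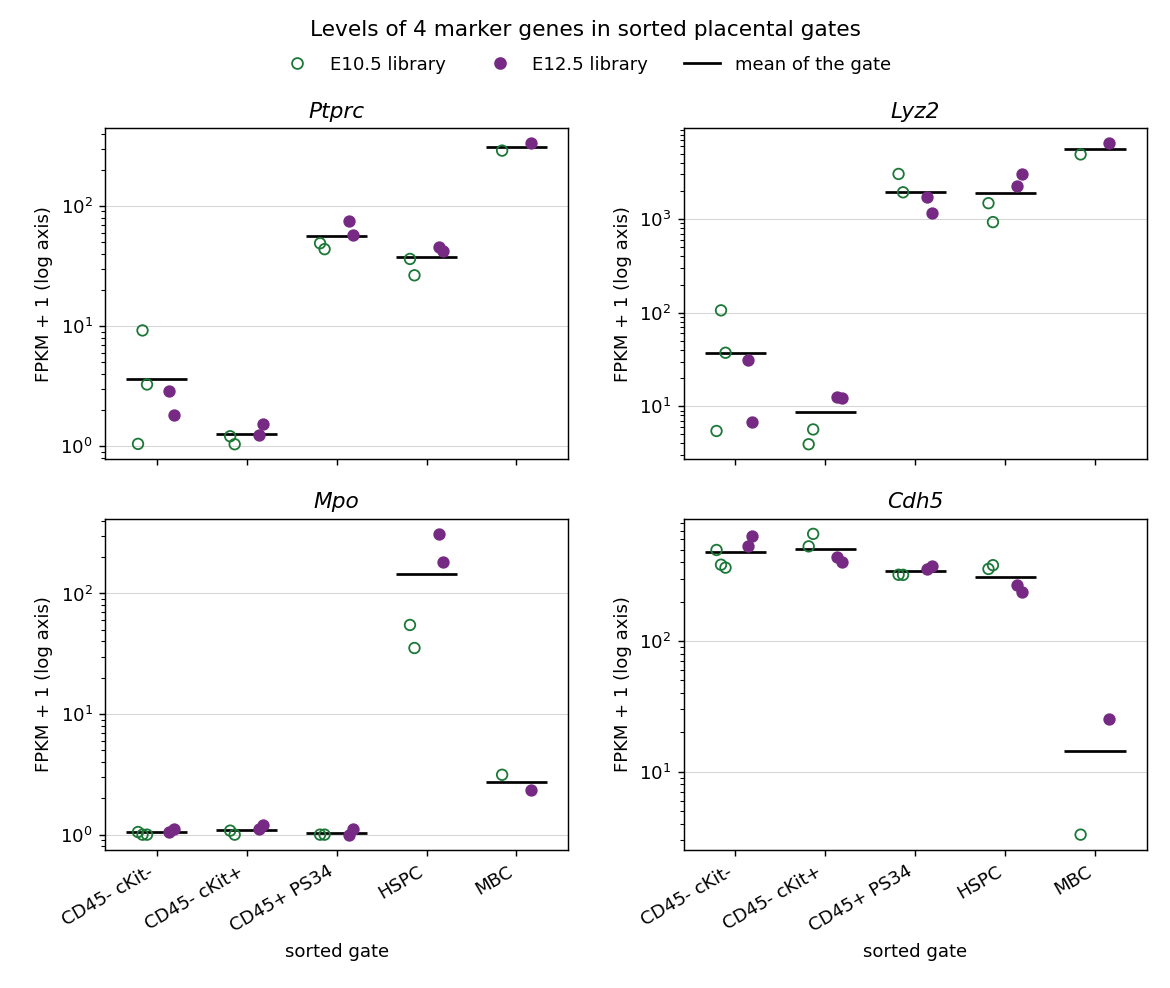
Levels of Ptprc, Lyz2, Mpo and Cdh5 in each of the 19 bulk libraries (points; vertical axis, FPKM + 1 on a log axis; horizontal axis, gate) with open symbols for E10.5, filled symbols for E12.5 and a bar at the gate mean. Ptprc averaged 0.255 FPKM in CD45- cKit+ and 55.2 in CD45+ PS34 libraries, while Cdh5 averaged 310 FPKM in HSPC and 342 in CD45+ PS34 libraries.

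The fourth comparison set HSPC against CD45+ PS34, both of which carry CD45. Granulocyte-monocyte genes separated them: Mpo was at 145 ± 128 FPKM in HSPC and 0.0282 ± 0.0564 in CD45+ PS34 (log2 fold change 6.64 ± 0.23, n = 4 each; adjusted p = 1.09e-08), and Prtn3, which encodes proteinase 3, at 43.5 ± 19.6 and 0.0615 ± 0.123 FPKM (5.28 ± 0.25; adjusted p = 2.91e-07). With Elane (2.04) and Ms4a3 (1.92), 4 of 12 genes of this list rose and 0 fell (5 adjusted over the list alone, adjusted p = 1.04e-05). Prg2, the eosinophil granule protein gene, was at 83.8 ± 107 FPKM in HSPC and listed at 0 in all CD45+ PS34 libraries. Phgdh, the first enzyme of serine synthesis, rose by 3.39 ± 0.32 (34.3 ± 4.99 against 2.99 ± 3.11 FPKM, adjusted p = 0.000253), and Mpl, the thrombopoietin receptor gene, by 2.02 ± 0.28 (4.25 ± 2.9 against 0.167 ± 0.333 FPKM, adjusted p = 0.00435). The mast cell gene Cpa3 rose by 3.26 and the fetal stem cell regulator Hmga2 by 2.61, both without a call when only these groups were fitted. Of 12 fetal-program genes 2 rose (Hmga2 and Igf2bp3 by 1.51) and 0 fell (3 adjusted over the list alone, adjusted p = 0.000265, or adjusted p = 0.176 with an estimated correlation); the count was 1 without library 1 of E10.5 or E12.5 HSPC. Levels of Prom1 (-0.64; adjusted p = 0.266), Cd34 (0.14; adjusted p = 0.714), Kit (0.67; adjusted p = 0.277), Ptprc (-0.58; adjusted p = 0.595) and Etv6 (0.14; adjusted p = 0.634) were not called different.

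Proliferation genes were higher and stress genes lower in HSPC. Of 20 cell-cycle genes 3 rose (Mcm5 by 0.94, the topoisomerase gene Top2a by 0.90 and Mcm2 by 0.78) and 0 fell, against 12 adjusted over the list alone (adjusted p = 4.28e-09). Of 16 stress genes 4 fell (Hspa1b by 1.05, Egr1 by 0.71, Dusp1 by 0.49 and Klf6 by 0.48) and 0 rose, against 12 adjusted over the list alone (adjusted p = 1.19e-12, or adjusted p = 0.0747 with an estimated correlation). Of 19 interferon genes 4 fell (Ifitm3 by 0.83 ± 0.11, Isg15 by 0.83, Oasl2 by 0.63 and Irf7 by 0.50) and 0 rose, against 5 adjusted over the list alone (adjusted p = 5.01e-06, or adjusted p = 0.0747 with an estimated correlation). Of 17 trophoblast genes 1 fell (Epcam by 1.46) and 0 rose, against 6 adjusted over the list alone (adjusted p = 4.3e-05, or adjusted p = 0.0548 with an estimated correlation). The 17 endothelial genes gave no called member (2 rose adjusted over the list alone, adjusted p = 0.917), with a median of -0.111 and a mean of 0.022. Cdh5 was at 310 ± 68 FPKM in HSPC and 342 ± 26.5 in CD45+ PS34 (-0.16 ± 0.12; adjusted p = 0.533).

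These calls rested on few libraries. In all, 327 genes were called, 181 higher and 146 lower in HSPC. The total was 190 and 189 without E10.5 cKit+ libraries 1 and 2, 178 without E10.5 CD45+ PS34 library 2, 104 and 152 without E10.5 HSPC libraries 1 and 2, 193 and 194 without E12.5 cKit+ libraries 1 and 2, and 111 and 93 without E12.5 HSPC libraries 1 and 2. With only the groups compared in the fit, it was 71, and the named cell-cycle, stress and fetal-program genes, Isg15, Oasl2, Irf7, Epcam and Cpa3 lost their calls. The cell-cycle count was 1 without E10.5 CD45+ PS34 library 2 or any HSPC library, 7 without E10.5 CD45+ PS34 library 1, and 5 without E10.5 cKit- library 2 or 3. The stress count was 1 without E10.5 CD45+ PS34 library 1, E10.5 HSPC library 2 or either E12.5 HSPC library, and 2 without E10.5 HSPC library 1 or E12.5 CD45+ PS34 library 1. The interferon count was 2 without either E10.5 HSPC library or E12.5 HSPC library 1, and 1 without E12.5 HSPC library 2. The trophoblast count was 3 without E10.5 cKit- library 1 and 2 without E12.5 CD45+ PS34 library 1. Epcam kept its call only without an E10.5 cKit- library, E12.5 CD45+ PS34 library 1 or an MBC library. Hspa1b lost its call without any E12.5 library of the CD45- gates as well as without E10.5 or E12.5 CD45+ PS34 library 1 or any HSPC library. Mcm2 and Klf6 also lost theirs without E12.5 CD45+ PS34 library 2.

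The next question was what changed from E10.5 to E12.5 within the CD45- PS34 gates. Ly6a, which encodes the Sca1 antigen of the gate, fell by 1.97 ± 0.19 (545 ± 303 FPKM at E12.5, n = 4, against 1923 ± 304 at E10.5, n = 5; adjusted p = 6.81e-05). Fetal-program genes rose, among them the imprinted growth factor gene Igf2 (3.45 ± 0.26; 2261 ± 525 against 211 ± 112 FPKM, adjusted p = 1.43e-05) and the imprinted RNA H19 (2.77). Of 12 such genes 8 rose and 0 fell (9 adjusted over the list alone, adjusted p = 7.46e-09, or adjusted p = 0.112 with an estimated correlation). The imprinted gene Magel2 rose by 4.08 ± 0.53. The placental hormone genes Prl2b1 (5.82 ± 0.98; 166 ± 124 against 0.998 ± 1.76 FPKM, adjusted p = 0.00263) and Prl3b1 (5.21 ± 0.74; 158 ± 94.3 against 3.95 ± 3.35 FPKM, adjusted p = 0.000989) rose with them. Of 17 trophoblast genes 4 rose (Prl3b1, Tpbpa by 3.96, Krt19 by 1.04 and Krt8 by 0.97) and 1 fell (Prl3d1 by 2.77, a hormone gene of trophoblast giant cells). This list gave 6 rises and 1 fall adjusted over the list alone and adjusted p = 0.00105, or adjusted p = 0.119 with an estimated correlation. Tdo2, a tryptophan-degrading enzyme gene of the decidua, fell by 4.35 ± 0.45 (2.36 ± 3.43 against 51 ± 27.7 FPKM, adjusted p = 1e-04), and Cxcl14, A2m, Penk, Gatm and Slc6a12 fell by 3.21 to 4.10.

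Endothelial genes moved both ways in these gates: 2 of 17 rose and 4 fell (3 and 6 adjusted over the list alone, adjusted p = 0.651), with a median of -0.305 and a mean of 0.014. Clec14a rose by 2.54 ± 0.23 (54.8 ± 26 against 8.44 ± 2.31 FPKM, adjusted p = 4.45e-05) and Plvap, a diaphragm protein gene of fenestrated endothelium, by 1.16 ± 0.15 (535 ± 90.9 against 232 ± 69.5 FPKM, adjusted p = 0.000505). Egfl7 (-0.87), Emcn (-0.76), Sox18 (-0.75) and Sox17 (-0.53) fell. Sox18 lost its call with a pseudocount of 0.1 and without any E10.5 library except cKit- library 3 and the MBC library, E12.5 cKit- library 1 or either E12.5 cKit+ library, and Sox17 without either E10.5 cKit+ library, E12.5 cKit- library 1 or either E12.5 cKit+ library. The arterial genes Gja4 and Unc5b rose by 2.07 ± 0.23 and 1.57 ± 0.16, while the Notch target Hes1 fell by 1.23 and the blood and endothelial regulator Lmo2 by 1.04 ± 0.19. Of 16 mesenchyme genes 3 fell (Des by 2.18 ± 0.31, Rgs5 by 1.98 and Pdgfra by 1.27) and 2 rose (Acta2 by 1.81 and Tagln by 1.26; 5 fell and 2 rose adjusted over the list alone, adjusted p = 0.119). Pdgfra lost its call without any library of these gates except E10.5 cKit- library 3 or without either E10.5 HSPC library. Rgs5 lost its call without any library of these gates except the 3 of E10.5 cKit- and E12.5 cKit- library 2, and was at -1.22 without E12.5 cKit- library 1. Of 19 interferon genes 11 fell and 0 rose (1 rose and 11 fell adjusted over the list alone, adjusted p = 4.24e-07, or adjusted p = 0.112 with an estimated correlation), among them Ifitm3 by 1.04 ± 0.10 (614 ± 248 against 1195 ± 87.9 FPKM). Among the 20 cell-cycle genes, 6 rose, including Top2a by 0.73, and 0 fell (7 rose and 1 fell adjusted over the list alone, adjusted p = 0.00146, or adjusted p = 0.199 with an estimated correlation). Kit (-0.19; adjusted p = 0.764) and Cd34 (-0.23; adjusted p = 0.405) were not called.

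In all, 1523 genes were called in the CD45- gates, 720 higher and 803 lower at E12.5 (47.3% higher), against 769 and 751 under quantile normalization and 793 and 756 under median-ratio scaling. The total was 828 and 807 without E10.5 cKit+ libraries 1 and 2, 893 and 925 without E12.5 cKit- libraries 1 and 2, and 843 and 737 without E12.5 cKit+ libraries 1 and 2. The fetal-program count was 4 without E10.5 cKit+ library 2 and 5 without E12.5 cKit- library 1 or either E12.5 cKit+ library. The interferon count was 7 without either E10.5 cKit+ library or E12.5 cKit- library 1, and 6 without E12.5 cKit+ library 2. The cell-cycle count was 1 or 2 without any E10.5 cKit+, E12.5 cKit- or E12.5 cKit+ library, and so was the trophoblast count. Tpbpa lost its call without library 1 of either cKit+ group, and Prl3d1 without any E12.5 library of these gates or E10.5 cKit+ library 2. Krt19 lost its call without any E10.5 cKit+, E12.5 cKit- or E12.5 cKit+ library, and Krt8 without those, E10.5 cKit- library 1 or 3, either E10.5 HSPC library or either E12.5 CD45+ PS34 library.

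**Figure D2:**
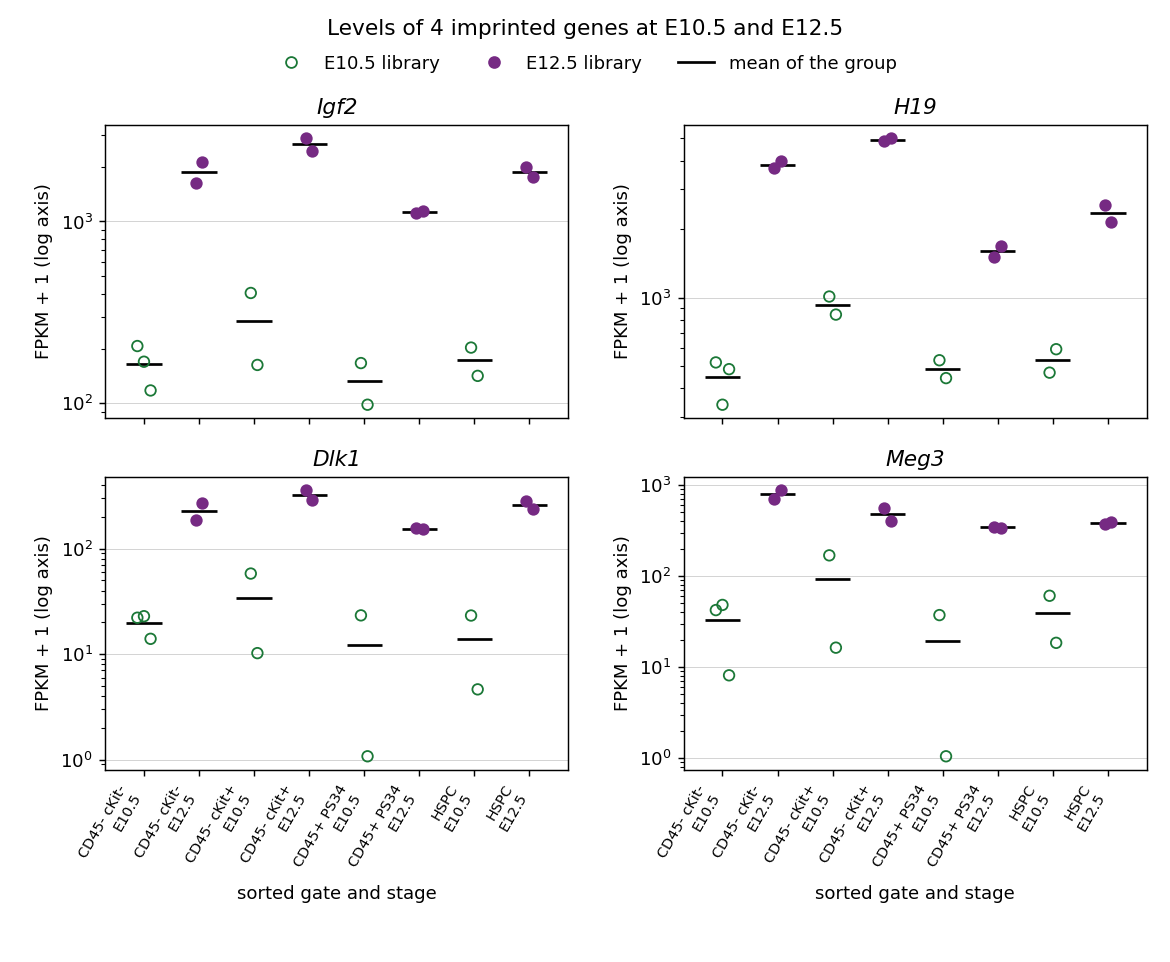
Levels of Igf2, H19, Dlk1 and Meg3 in each bulk library of the 4 gates compared (points; vertical axis, FPKM + 1 on a log axis; horizontal axis, gate and stage) with a bar at the group mean. Igf2 averaged 211 FPKM at E10.5 and 2261 at E12.5 in the CD45- gates, and 151 and 1498 FPKM in the CD45+ gates.

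The same stage comparison in the 2 CD45+ gates, CD45+ PS34 and HSPC, gave a fall of Ly6a of 2.49 ± 0.20 (596 ± 281 against 3223 ± 988 FPKM, n = 4 each; adjusted p = 2.67e-05). Igf2 rose by 3.30 ± 0.27 (1498 ± 445 against 151 ± 43.8 FPKM, adjusted p = 3.32e-05) and Dlk1, an imprinted Notch-family ligand gene, by 4.79 ± 0.81 (206 ± 62.9 against 12.1 ± 11.9 FPKM, adjusted p = 0.00292). Of 12 fetal-program genes 7 rose and 0 fell (9 adjusted over the list alone, adjusted p = 1.33e-08, or adjusted p = 0.0664 with an estimated correlation). Of 12 stem cell surface genes 4 rose and 0 fell (6 adjusted over the list alone, adjusted p = 0.000371, or adjusted p = 0.107 with an estimated correlation): the progenitor receptor gene Flt3 by 1.90 ± 0.26 (5.42 ± 2.83 against 0.659 ± 0.599 FPKM, adjusted p = 0.000733), Itga2b by 1.72 ± 0.30, Itga4 by 1.05 and Cd93 by 0.69. Cd93 lost its call without library 2 of E10.5 CD45+ PS34 or E10.5 HSPC. Of 12 granulocyte-monocyte genes 4 rose and 0 fell (4 adjusted over the list alone, adjusted p = 0.00052, or adjusted p = 0.0664 with an estimated correlation): Mpo by 1.26, the haptoglobin gene Hp by 1.21 ± 0.23 (41.1 ± 9.11 against 17.5 ± 5.33 FPKM, adjusted p = 0.00523), Ms4a3 by 1.17 and Elane by 0.78. Mpo, Ms4a3 and Elane lost their calls with a pseudocount of 0.1, and Elane also without E10.5 HSPC library 2. Of 7 mast and basophil genes 3 rose and 0 fell (3 adjusted over the list alone, adjusted p = 0.00197, or adjusted p = 0.14 with an estimated correlation): Cpa3 by 3.68 ± 0.46 (65.3 ± 77 against 0.883 ± 1.39 FPKM, adjusted p = 0.000422), Hdc by 2.11 ± 0.36 and Ms4a2 by 1.35.

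Of 20 cell-cycle genes 8 rose, including Top2a by 0.91, and 1 fell (11 and 1 adjusted over the list alone, adjusted p = 2.33e-07, or adjusted p = 0.0664 with an estimated correlation). The one that fell was Rrm2, a subunit gene of the enzyme that makes DNA precursors, by 2.42 ± 0.31 (89 ± 16.3 against 492 ± 148 FPKM, adjusted p = 0.000472). Tdo2 fell by 4.73 ± 0.47 (12 ± 9.02 against 339 ± 205 FPKM, adjusted p = 0.000123), and the mesenchyme genes Des by 3.05 ± 0.32 (76 ± 23.1 against 667 ± 290 FPKM, adjusted p = 0.000163) and Rgs5 by 3.67 ± 0.53. Of 16 mesenchyme genes 4 fell and 1 rose (Lum by 2.87; 6 fell and 2 rose adjusted over the list alone, adjusted p = 0.0431, or adjusted p = 0.655 with an estimated correlation). Dio3, the thyroid hormone-inactivating enzyme gene, fell by 5.45 ± 0.51 (1.6 ± 1.3 against 113 ± 73.6 FPKM, adjusted p = 9.41e-05), and the posterior Hox genes Hoxa10 and Hoxa11 by 2.79 ± 0.50 and 2.52 ± 0.29. Clec14a (1.79 ± 0.24) and Gja4 (2.14 ± 0.24) rose, and Lmo2 (-1.11 ± 0.20) and the Notch target Hes1 (-1.20 ± 0.20) fell. Several of these transcripts were scarce in single E12.5 HSPC, where Igf2 averaged 4.06 FPKM (206 in E12.5 PS34 cells), Dlk1 0.624 (9.16), Des 0.15 (151), Clec14a 0.0129 (20.8) and Gja4 0.0301 (28.9). The changes are those of the sorted libraries and are not assigned to HSPC themselves. Kit (-0.54; adjusted p = 0.288), Ptprc (0.50; adjusted p = 0.593) and Gfi1b (0.56; adjusted p = 0.451) were not called. In all, 1331 genes were called, 588 higher and 743 lower at E12.5. The total was 766 without E10.5 HSPC library 2, and 734 and 886 without E12.5 HSPC libraries 1 and 2. The fetal-program count was 4 without E10.5 HSPC library 2 or E12.5 HSPC library 1. The cell-cycle count was 4 without library 1 of E10.5 or E12.5 HSPC and 5 without E12.5 HSPC library 2.

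The MBC gate, CD45+ but without CD34 and cKit, was set against HSPC with 1 library a stage, so each lone library was taken to vary as the other groups do. Prf1, the perforin gene of killer lymphocytes, rose by 7.80 ± 1.48 (547 ± 402 FPKM, n = 2, against 1.27 ± 0.989, n = 4; adjusted p = 0.00116), and the granzyme genes Gzmf, Gzmd and Gzme by 5.29 to 6.04. Of 9 lymphoid genes 8 rose and 0 fell (8 adjusted over the list alone, adjusted p = 5.18e-05), including the B-cell receptor gene Cd79a by 4.37 ± 0.69 (46.5 ± 35.3 against 1.11 ± 0.795 FPKM, adjusted p = 0.000316) and Cd19 by 3.49 ± 0.42. Of 19 interferon genes 15 rose and 1 fell (Ifi44 by 1.18; 15 and 2 adjusted over the list alone, adjusted p = 6.47e-07), with Irf7 up by 2.02 ± 0.12 (602 ± 4.65 against 148 ± 13.6 FPKM, adjusted p = 5.58e-08). Of 18 macrophage genes 8 rose, including Cx3cr1 (2.89 ± 0.50) and Aif1 (2.85 ± 0.44), and 1 fell (C1qc by 1.49; 8 and 1 adjusted over the list alone, adjusted p = 0.00161, or adjusted p = 0.452 with an estimated correlation). C1qc lost its call without E10.5 HSPC library 1 or E12.5 HSPC library 2. Ptprc rose by 3.07 ± 0.59 (309 ± 29.9 against 36.6 ± 8.35 FPKM, adjusted p = 0.00128).

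All 17 endothelial genes fell in MBC (17 adjusted over the list alone, adjusted p = 3.59e-21), as did 11 of 14 arterial genes (11 adjusted over the list alone, adjusted p = 2.16e-06) and 4 of 5 venous genes (Flt4, Ephb4, Nr2f2 and Nrp2; 5 adjusted over the list alone, adjusted p = 0.000478). The 1 arterial gene that rose was Cxcr4 (2.47), which leukocytes share. Plvap fell by 5.49 ± 0.19 (21.7 ± 29 against 446 ± 106 FPKM, adjusted p = 7.66e-10). The gate genes Cd34 (-4.72 ± 0.19; 9.95 ± 8.31 against 244 ± 32.2 FPKM, adjusted p = 2.38e-09), Kit (-3.46 ± 0.35), Ly6a (-3.01 ± 0.24) and Prom1 (-1.82 ± 0.34) fell. The 5 gate genes gave adjusted p = 0.00612 (1 rose and 4 fell), which follows from sorting on CD34 and cKit. Among the 20 cell-cycle genes, 19 fell and 0 rose (19 adjusted over the list alone, adjusted p = 3.84e-08), Rrm2 by 4.22 ± 0.38. Of 12 fetal-program genes 10 fell and 0 rose (10 adjusted over the list alone, adjusted p = 1.73e-05, or adjusted p = 0.0848 with an estimated correlation), Igf2 by 4.54 ± 0.33. Of 16 mesenchyme genes 11 fell, Des by 4.94 ± 0.40 among them, and 1 rose (Thy1 by 3.62; 11 and 1 adjusted over the list alone, adjusted p = 0.000478, or adjusted p = 0.238 with an estimated correlation). Plvap, Igf2 and Des were scarce in single E12.5 HSPC, so such falls are not assigned to HSPC. Mpo fell by 5.24 ± 0.28 (1.74 ± 0.567 against 145 ± 128 FPKM, adjusted p = 2.49e-08). Of the 4 conversion factors, Gata2 fell by 2.96 ± 0.41, Fos by 0.49 (below a log2 change of 1), and Etv6 rose by 1.39 ± 0.16 (68.7 ± 8.25 against 25.8 ± 4.77 FPKM, adjusted p = 1.81e-05). In all, 4981 genes were called, 2520 higher and 2461 lower in MBC (50.6% higher). The split was 2320 and 2267 under quantile normalization, and 2162 and 2821 under median-ratio scaling (43.4% higher).

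**Figure D3:**
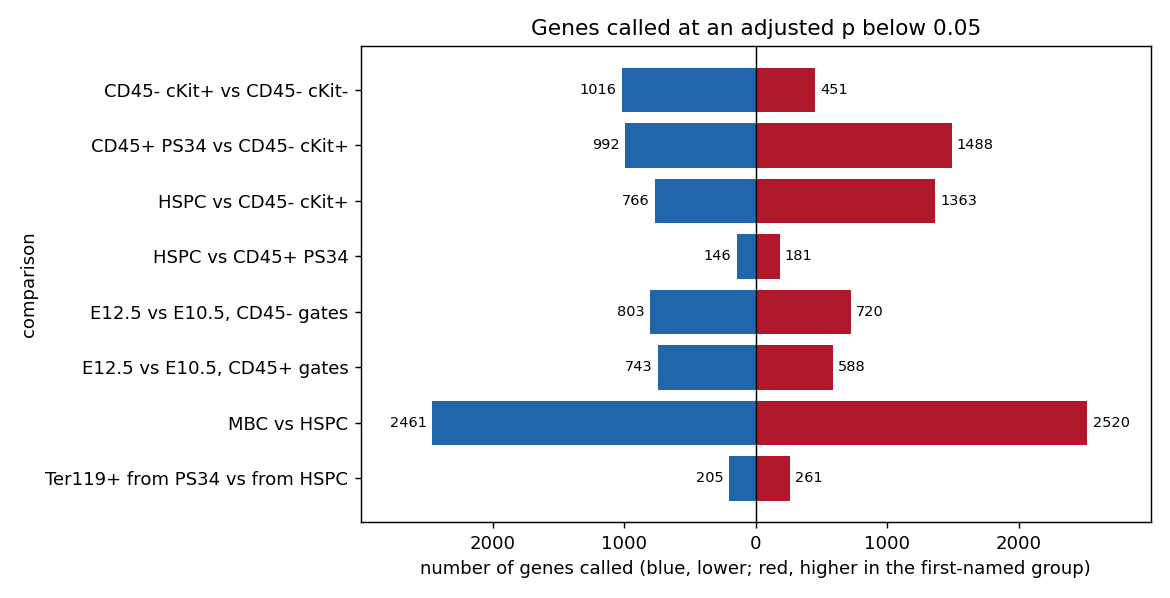
Genes called in each bulk comparison and in the Ter119+ comparison (horizontal bars, number of genes from 0), split into higher (right) and lower (left) in the first-named group. The counts run from 327 for HSPC against CD45+ PS34 (181 higher, 146 lower) to 4981 for MBC against HSPC.

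Lists that were called in none of the 8 comparisons, the 7 bulk ones averaged over stage or gate and the Ter119+ one, were the endoderm (lowest adjusted p = 0.324), erythroid (0.317), heme synthesis (0.27), embryonic globin (0.176), stem cell regulator (0.112) and conversion factor (0.117) lists. The endoderm and embryonic globin lists could be tested in the 7 bulk comparisons only. Of them, 1 endoderm gene passed the filter in the Ter119+ table, which held 0 of the 3 embryonic globin genes. Adult globin had too few genes above the filter to test as a list. The megakaryocyte list was called in 3 of the 8 comparisons (lowest adjusted p = 0.0165) and the Hoxa list in 1 (adjusted p = 0.0435). Neither was called in any with an estimated correlation. Over these 8 comparisons 58 of 186 list tests passed, and 16 passed with an estimated correlation. In the 4 tests of whether a bulk contrast differed between stages or gates, 28 of 96 list tests passed, and 3 passed with an estimated correlation: the arterial list for cKit (adjusted p = 0.0443 with an estimated correlation) and the granulocyte-monocyte and trophoblast lists for HSPC against CD45- cKit+ (adjusted p = 0.0304 with an estimated correlation for each). Among the others were the stem cell regulator list for HSPC (adjusted p = 0.00887) and cKit (adjusted p = 0.0251), the megakaryocyte list for cKit (adjusted p = 0.00678) and the Hoxa list for stage in the CD45+ against the CD45- gates (adjusted p = 0.0365).

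The Ter119 comparison asked whether cells carrying this erythroid antigen differ with their source after the same culture. Both sources gave libraries with high macrophage and mast cell RNA and low erythroid RNA. Lyz2 stood at 23510 to 30300 FPKM and Cd68 at 888 to 1286 FPKM over the 4 libraries, and the mast cell proteases Cpa3 and Tpsb2 at 890 to 5742 and 978 to 7189 FPKM. Gypa, which encodes the protein next to which the Ter119 antigen lies, stood at 0 to 4.4 FPKM and the erythroid regulator Klf1 at 0 to 1.51 FPKM, while the transferrin receptor gene Tfrc stood at 86.1 to 107 FPKM. Hba-a1, Hbb-b1 and Hba-a2 were at 241.4, 184 and 35.24 FPKM in HSPC-derived library 1. Hbb-b2 was at 25.58 FPKM in PS34-derived library 1 and Hbb-b1 at 24.81 in PS34-derived library 2. Other values of these 4 adult globin genes were at most 0.00898 FPKM or listed at 0, which can be a failed estimate. HSPC-derived library 1 was also highest for Alas2 (16.8 FPKM), Car2 (26.64), Slc4a1 (6.243) and Gypa (4.4). It was lowest for Gata1 (11.22), and Klf1, Epor, Ermap and Rhag were higher in another library.

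In cells from PS34, against cells from HSPC, the neutrophil gene S100a9 (mm9, chromosome 3, 90496554 to 90499613) rose by 9.75 ± 0.24, at 999 ± 25.7 FPKM against 0.175 ± 0.247 (n = 2 each; adjusted p = 6.91e-05), and Mpo (mm9, chromosome 11, 87607285 to 87617914) by 4.71 ± 0.41, at 26 ± 4.31 against 0.0254 ± 0.036 FPKM (adjusted p = 0.00624). Stfa2 and BC100530 were at 350 ± 62.9 and 203 ± 24.7 FPKM and listed at 0 in HSPC-derived cells. The stromal chemokine gene Cxcl12 (mm9, chromosome 6, 117118552 to 117131386) fell by 6.35 ± 0.34, at 6.69 ± 2.43 against 634 ± 237 FPKM (adjusted p = 0.00124). Ly6a (mm9, chromosome 15, 74825306 to 74828461) fell by 4.28 ± 0.30, at 14 ± 3.29 against 295 ± 102 FPKM (adjusted p = 0.00373), and Hp by 4.25 ± 0.32. Of 11 mesenchyme genes 7 fell and 1 rose (1 rose and 8 fell adjusted over the list alone, adjusted p = 1.02e-06, or adjusted p = 0.495 with an estimated correlation). The collagen gene Col3a1 fell by 4.47 ± 0.35 (adjusted p = 0.00483) and Lum by 4.88 ± 0.41. Thy1, which T cells and stroma both carry, rose by 4.33 and was listed at 0 in both HSPC-derived libraries. The count of 7 that fell was 3 and 4 without HSPC-derived libraries 1 and 2. The cells had been grown on OP9 stroma, so stromal RNA left in the samples cannot be told apart from a difference by source. Of 16 stress genes 6 rose and 0 fell (13 adjusted over the list alone, adjusted p = 1.41e-11, or adjusted p = 0.495 with an estimated correlation), with Junb up by 1.39. It was 10 and 12 without HSPC-derived libraries 1 and 2, and 1 and 0 without PS34-derived libraries 1 and 2, where Junb lost its call. Of 10 mast and basophil genes, 2 rose (Mcpt8 by 6.56 and Prss34 by 5.02) and 1 fell (Fcer1a, -6.54; 3 and 7 adjusted over the list alone, adjusted p = 0.227); Prss34 lost its call without PS34-derived library 1. Of 16 macrophage genes, 2 rose (Itgam by 2.98 and Mrc1 by 1.59) and 2 fell (C1qb by 4.38 and C1qc by 3.77; adjusted p = 0.117), with a median of 0.302 and a mean of -0.093. C1qb and C1qc were listed at 0 in both PS34-derived libraries, and a 0 can be a failed estimate. Mrc1, C1qb and C1qc lost their calls without either PS34-derived library. Thy1 and these mast cell and macrophage genes also lost theirs with no filter on low values. Of 20 cell-cycle genes 1 fell (Pcna by 0.95; adjusted p = 0.0118, or adjusted p = 0.495 with an estimated correlation), a call lost without either PS34-derived library, and the count was 2 without HSPC-derived library 2. In all, 466 of 11448 genes were called, 261 higher and 205 lower in cells from PS34, with 2 residual degrees of freedom. The total was 913 without HSPC-derived library 2, 144 and 124 without PS34-derived libraries 1 and 2, and 67 with no filter on low values.

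**Figure D4:**
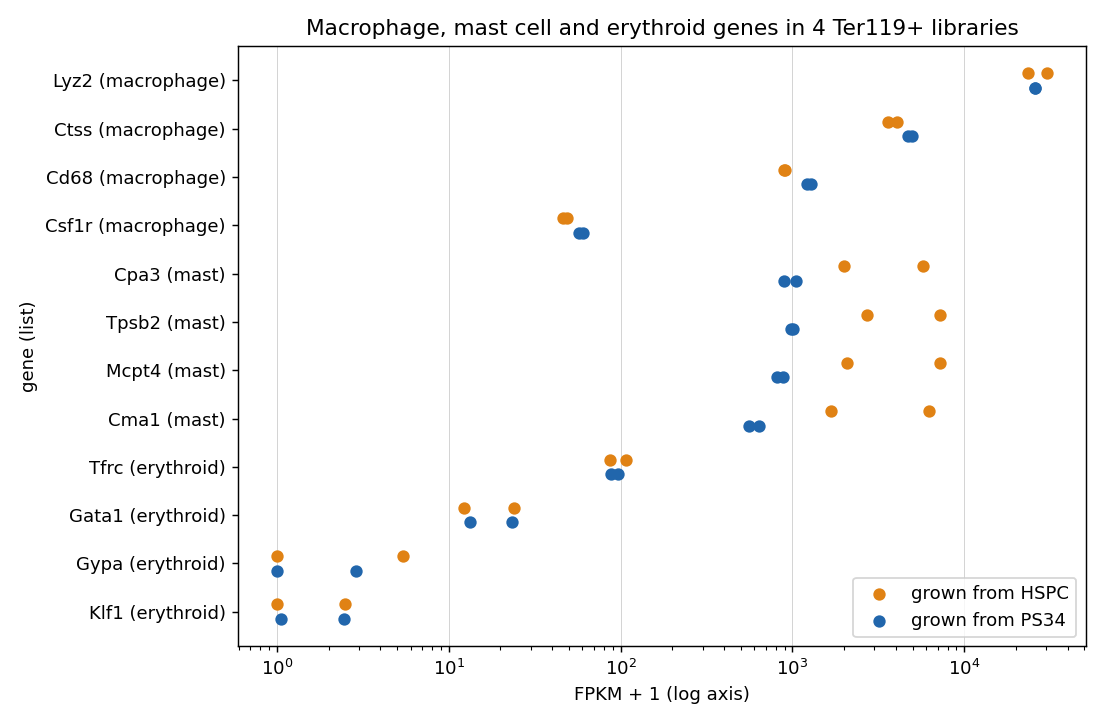
Levels of 12 macrophage, mast cell and erythroid genes in the 4 Ter119+ libraries (points; horizontal axis, FPKM + 1 on a log axis; vertical axis, gene), coloured by source. Lyz2 lies between 23510 and 30300 FPKM and Gypa between 0 and 4.4 FPKM.

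The single cells show which genes the sorted CD45- PS34 cells carry cell by cell. Each group of 48 cells came with no animal named, so it counts as 1 sample, and no test between groups was made. Intervals are exact Clopper-Pearson 95% intervals and cover counting error only. The endothelial cadherin gene Cdh5 was at 1 FPKM or more in 47 of 48 cells at both E10.5 and E12.5 PS34, and in 3 of 48 E12.5 HSPC (6.25%, 1.31 to 17.2%). Of 18 endothelial genes, the median cell held 16 in E10.5 PS34, 15 in E12.5 PS34 and 3 in HSPC. Ptprc was found in 0 of 48 E10.5 PS34 cells, with an interval of up to 7.4%, and in 1 of 48 at E12.5. It was found in 42 of 48 HSPC (87.5%, 74.8 to 95.3%). Kit was found in 38 of 48 E10.5 PS34 cells (79.2%, 65 to 89.5%), 41 of 48 at E12.5 (85.4%, 72.2 to 93.9%) and 34 of 48 HSPC (70.8%, 55.9 to 83.1%). Prom1 was found in 28, 25 and 1 of 48 cells in these groups. Ly6a was found in 47 and 45 of 48 PS34 cells, at means of 1357 and 839.8 FPKM, and in 17 of 48 HSPC (35.4%, 22.2 to 50.5%).

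Runx1 was at 1 FPKM or more in 9 of 48 PS34 cells at each stage (18.8%, 8.95 to 32.6%) and in 41 of 48 HSPC. In E10.5 PS34 all 9 cells with Runx1 also held Cdh5, and at E12.5 it was 8 of 9. Myb was in 0 of 48 E10.5 PS34 cells, 1 of 48 at E12.5 and 35 of 48 HSPC (72.9%, 58.2 to 84.7%). Other blood regulators went either way: from E10.5 PS34 cells to HSPC, Ikzf1 was in 1 and 32 of 48, Lyl1 in 14 and 28, Meis1 in 10 and 27, Fli1 in 47 and 38 and Mecom in 32 and 1. The median cell held 8 (E10.5 PS34), 6 (E12.5 PS34) and 10 (HSPC) of 21 stem cell regulator genes. Of the conversion factors, Gata2 was in 42, 32 and 36 of 48 cells of E10.5 PS34, E12.5 PS34 and HSPC, Etv6 in 31, 30 and 40, Fos in 47, 48 and 40, and Gfi1b in 1, 5 and 16 (33.3%, 20.4 to 48.4%). Mpo was in 0 of 48 E10.5 PS34 cells, 34 of 48 E12.5 PS34 cells (70.8%, 55.9 to 83.1%; mean 80.5, median 2.29 and highest 3456 FPKM) and 46 of 48 HSPC (95.8%, 85.8 to 99.5%; mean 509 FPKM). Counted from 5 FPKM, Mpo was in 20.8% of E12.5 PS34 cells and 87.5% of HSPC. Of the 34 Mpo-bearing E12.5 PS34 cells, 33 held Cdh5. The bulk libraries conflict with this, as Mpo averaged 0.0847 FPKM in E12.5 CD45- cKit- and 0.158 in CD45- cKit+ libraries, and nothing tested here tells which table is right. The platelet chemokine gene Pf4 was in 3 of 48 E10.5 PS34 cells, 26 of 48 at E12.5 (54.2%, 39.2 to 68.6%; 29.2% from 5 FPKM) and 10 of 48 HSPC. The median cell held 8.5, 6.5 and 17 of 20 cell-cycle genes in the 3 groups, and 1 of 19 trophoblast genes in each. From E10.5 to E12.5 PS34 cells, the largest mean log2 differences were Igf2 (3.13), Meg3 (3.08) and H19 (2.80) upward, and Smagp (-3.53), Cxcl1 (-3.19) and Timp1 (-3.01) downward. From E12.5 PS34 to HSPC they were Tyrobp (7.48) and Coro1a (6.68) upward, and Sparc (-9.58) and Ecscr (-8.68) downward.

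**Figure D5:**
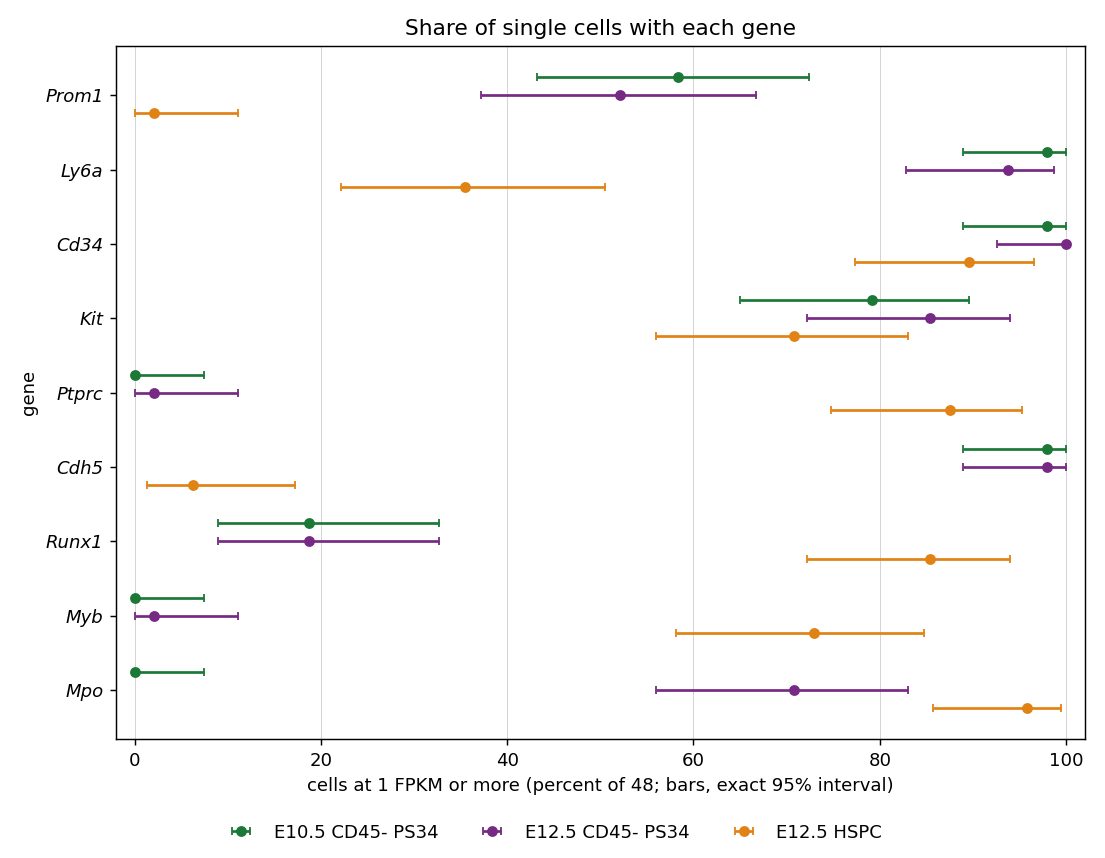
Share of the 48 cells of each single-cell group at 1 FPKM or more (points; horizontal axis, percent of cells; vertical axis, gene) with exact Clopper-Pearson 95% intervals as bars. Cdh5 reaches 97.9% in both PS34 groups and 6.25% in HSPC, and Ptprc 0% in E10.5 PS34 and 87.5% in HSPC.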

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

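The tests of explanations for the 3 patterns below were chosen only after the results were seen, while the counts over other splits of the libraries were planned before the data were examined.

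Contrasts that differed between stages or gates were found by testing the difference itself. The difference between cKit+ and cKit- cells changed from E10.5 to E12.5 for 99 genes (15 higher and 84 lower at E12.5). The von Willebrand factor gene Vwf was 1.07 higher in cKit+ cells at E10.5 (not called) and 2.38 lower at E12.5, a change of -3.45 ± 0.49 (adjusted p = 0.0111) that lost its call without E10.5 cKit+ library 2 or E12.5 cKit- library 2. The count of 99 was 247 without E10.5 cKit- library 1, 41 and 4 without E10.5 cKit+ libraries 1 and 2, 44 and 12 without E12.5 cKit- libraries 1 and 2, and 35 and 11 without E12.5 cKit+ libraries 1 and 2. Lists that changed toward higher values in cKit+ cells at E12.5 were cell cycle (median 0.51, adjusted p = 0.000449), mesenchyme (1.62, adjusted p = 0.00917) and trophoblast (0.80, adjusted p = 0.0148). Toward lower values went the arterial, endothelial, interferon (-0.57, adjusted p = 1.99e-05), megakaryocyte (-1.10, adjusted p = 0.00678), stress (-0.29, adjusted p = 0.015) and stem cell regulator (-0.44, adjusted p = 0.0251) lists. With an estimated correlation the arterial list alone of these kept its call, and the others had adjusted p of 0.143 to 0.484. Of 20 cell-cycle, 17 trophoblast, 16 stress and 20 regulator genes 0 were called. Among 16 mesenchyme genes 1 was higher, and 1 of 19 interferon and 1 of 13 megakaryocyte genes were lower. Of 14 arterial genes 2 were lower at E12.5 (Notch1 by 1.39 and Notch4 by 1.44; 9 adjusted over the list alone), and of 17 endothelial genes 1 (Cldn5 by 1.53; 8 adjusted over the list alone). The arterial count was 5 without E10.5 cKit- library 1, and 1 without E10.5 cKit+ library 1, either E10.5 HSPC library or E12.5 CD45+ PS34 library 1. It was 0 without E10.5 cKit- library 2 or 3, E10.5 cKit+ library 2, any E12.5 CD45- library or either E12.5 HSPC library. The endothelial count was 3 without E10.5 cKit- library 1 and 2 without any CD45+ PS34 library, and Cldn5 lost its call without any cKit+ library or either E12.5 cKit- library.

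The difference between CD45+ PS34 and CD45- cKit+ cells changed with stage for 248 genes (193 higher and 55 lower at E12.5). Slfn4, a myeloid gene of the interferon response, was higher in CD45+ PS34 by 1.75 at E10.5 and 5.81 at E12.5 (change 4.05 ± 0.32; adjusted p = 9.39e-05). Klf5 went the other way (change -4.70 ± 0.63; adjusted p = 0.00541). This count was 85 and 39 without E10.5 cKit+ libraries 1 and 2, and 98 and 35 without E12.5 cKit+ libraries 1 and 2. By list, the CD45 difference rose with stage for interferon (median 0.97, adjusted p = 6.69e-07), endothelial (0.72, adjusted p = 0.000216), stress (0.32, adjusted p = 0.00861) and arterial genes (0.59, adjusted p = 0.0424), and fell for macrophage (-0.91, adjusted p = 0.0092) and trophoblast genes (-1.35, adjusted p = 0.00892). None of these 6 lists passed with an estimated correlation (adjusted p of 0.215 to 0.462). Few members were called: 1 of 16 stress genes was higher, and of 14 arterial genes 0 were higher and 1 was lower. Of 18 macrophage and 17 trophoblast genes 0 were called. Of 19 interferon genes 6 were higher, Ifitm3 by 1.45 ± 0.22 among them (11 higher and 1 lower adjusted over the list alone), a count that was 2 without either E10.5 cKit+ library, 3 without E10.5 CD45+ PS34 library 2 or E12.5 cKit+ library 1, and 0 without E12.5 cKit+ library 2. Of 17 endothelial genes 3 were higher (Cldn5, Sox17 and Ecscr; 4 higher and 1 lower adjusted over the list alone), a count that was 0 without either E10.5 cKit+ library or E12.5 cKit+ library 2, and 1 without library 1 of E10.5 CD45+ PS34, E12.5 cKit+ or E12.5 CD45+ PS34.

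The difference between HSPC and CD45- cKit+ cells changed with stage for 82 genes (66 higher and 16 lower), among them Slfn4 (3.58 ± 0.32; adjusted p = 0.000239) and the mast cell receptor gene Ms4a2 (2.53 ± 0.33; adjusted p = 0.00376). It was 126 without E10.5 cKit- library 2, 34 and 21 without E10.5 cKit+ libraries 1 and 2, 50 and 24 without E10.5 HSPC libraries 1 and 2, 34 and 27 without E12.5 cKit+ libraries 1 and 2, and 37 and 29 without E12.5 HSPC libraries 1 and 2. By list it rose for granulocyte-monocyte (median 0.95, adjusted p = 1.7e-05), interferon (0.53, adjusted p = 6.59e-05), mast and basophil (0.51, adjusted p = 0.000675), stem cell regulator (0.26, adjusted p = 0.00887) and stem cell surface genes (0.37, adjusted p = 0.009), and fell for trophoblast (-2.08, adjusted p = 3.47e-07) and mesenchyme genes (-1.49, adjusted p = 0.00594). With an estimated correlation the granulocyte-monocyte and trophoblast lists passed, and the other 5 had adjusted p of 0.136 to 0.514. Members called higher were 2 of 12 granulocyte-monocyte, 2 of 7 mast and basophil and 1 of 19 interferon genes. The first 2 of these counts were 0 without either E12.5 HSPC library. Of 20 regulator, 12 surface, 17 trophoblast and 16 mesenchyme genes 0 were called.

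The change from E10.5 to E12.5 differed between the CD45- and CD45+ gates for 225 genes (133 higher and 92 lower in the CD45+ gates). Slfn4 rose more in the CD45+ gates (difference 3.22 ± 0.22; adjusted p = 5.58e-05), and Dio3 (-4.53 ± 0.71; adjusted p = 0.00907), the matrix gene Fbn1 (-3.96 ± 0.55; adjusted p = 0.00549) and Plvap (-1.33 ± 0.22; adjusted p = 0.0111) rose less or fell more there. This count was 345 and 351 without E10.5 cKit- libraries 1 and 2, 101 and 77 without E10.5 cKit+ libraries 1 and 2, and 101 without E10.5 HSPC library 2. It was 133 and 106 without E12.5 cKit- libraries 1 and 2, 74 and 83 without E12.5 cKit+ libraries 1 and 2, and 99 and 121 without E12.5 HSPC libraries 1 and 2. By list the change with stage was higher in the CD45+ gates for interferon (median 0.46, adjusted p = 0.000625), mast and basophil (1.35, adjusted p = 0.000679), granulocyte-monocyte (0.65, adjusted p = 0.00099) and stem cell surface genes (0.57, adjusted p = 0.00628), and lower for trophoblast (-1.16, adjusted p = 0.000625) and Hoxa genes (-1.08, adjusted p = 0.0365). None of these 6 lists passed with an estimated correlation (adjusted p of 0.135 to 0.194). Members called higher were 3 of 7 mast and basophil, 1 of 12 granulocyte-monocyte and 1 of 12 surface genes. The mast and basophil count was 0 without library 1 of E12.5 cKit+ or E12.5 HSPC. Of 19 interferon, 17 trophoblast and 6 Hoxa genes 0 were called.

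Endothelial transcripts stood high in the bulk HSPC libraries: at E12.5 Plvap was at 423 FPKM against 535 in the CD45- gates, Pecam1 at 275 against 359 and Cdh5 at 253 against 502. In single HSPC endothelial genes had a median of 0.433% (highest 13.7%) of their E12.5 PS34 level. That argues against HSPC carrying them only if the tables are comparable. Carry-over of the whole CD45- gate in proportion is argued against by the trophoblast genes, at a median of 8.97% of their CD45- level in bulk HSPC, below the lowest endothelial value of 38.6%. Carry-over of part of that gate stays open, since 7 of 8 mesenchyme genes reached 25% or more of their CD45- level in bulk HSPC (22.3 to 251%, median 56%) against a median of 0.557% in the single cells. Endothelial cells in the sorted samples remain a candidate source, although the CD45 gate would remove such cells. A check took 38 genes outside the marker lists, abundant in single E12.5 PS34 cells and below 1% of that level in single HSPC. Of these, 37 reached 25% or more of their CD45- level in bulk HSPC (Sparc 646 against 1043 FPKM). They were chosen by single-cell levels, so any mismatch of bulk and single-cell HSPC would give this count. It cannot tell endothelial cells from a difference between the tables. No biological explanation other than HSPC expression was tested.

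The Ter119+ libraries held few erythroid and many myeloid transcripts. Failed estimates of the globin genes alone are argued against by the other erythroid genes, whose median was at most 5.63% of the macrophage median in the 4 libraries. Macrophages and mast cells in the sorted samples are a candidate source that stays open: 12 of the 28 macrophage and mast cell genes reached 100 FPKM in all 4 libraries, fewer than the explanation needs and more than it forbids. Lyz2 (23510 to 30300 FPKM), Ctss (3608 to 4957 FPKM) and Tpsb2 (978 to 7189 FPKM) were among the most abundant, all 28 are genes that blood cultures can themselves express, and the Ter119 gate would remove such cells. Both sources gave this pattern, and no biological explanation was tested.

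Imprinted genes were higher at E12.5, 13 of the 24 tested in both the CD45- and the CD45+ gates and 0 lower in either, with medians of 1.57 and 1.73. Quantile normalization, under which 13 of 13 stayed called in both, argues against the submitters' scaling as the whole cause. Fewer maternal decidual cells at E12.5 could contribute. The 15 decidual genes tested had medians of -0.863 (CD45-) and -1.96 (CD45+ gates), on each side of this test's bound, so this stays open. Of that list's most abundant genes, Tdo2 went from 492 FPKM at E10.5 to 7.61 at E12.5 in HSPC. Cebpb was at 1690 FPKM in the E10.5 MBC library, so the list is not only decidual. CD34 gating would remove decidual cells without CD34, but the cKit- gate keeps those without cKit. A rise in every CD45- PS34 cell with embryonic stage, which the design names, also stays open, since 8 of 48 E10.5 cells reached the median imprinted score of the E12.5 cells, and in HSPC it could not be tested, as no E10.5 HSPC single cells were measured (E12.5 HSPC cells had a median score of 0.261 against 2.22 in E12.5 PS34).

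Other splits of the same libraries tested whether counts of called genes could be had by chance. Each was fitted with those libraries alone, 1 difference between the sides and a term for stage (or gate), so the real counts are not those of the report: for HSPC against CD45+ PS34 it is 7 in place of 327. What follows holds for these real counts only. For cKit+ against cKit- the real split gave 1020 genes and the other splits of 100 drawn at most 42. For CD45+ PS34 against CD45- cKit+ these counts were 1727 and 1. They were 2753 and 0 for HSPC against CD45- cKit+, and 7 and 1 for HSPC against CD45+ PS34. For stage they were 915 and 29 in the CD45- gates, and 679 and 1 in the CD45+ gates. In each comparison 1 split, the real one, reached its count. That is 1% of the splits for cKit and for stage in the CD45- gates, and 2.94% of 34 splits in the others. The other splits mix the sides, so a real difference adds to their spread and lowers their counts. Libraries are also not known to come from separate animals, so chance is not excluded. The MBC and Ter119+ comparisons had fewer than 3 libraries on a side and were not split.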

How the results depend on the processing

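Each result was refitted with other settings chosen before the data were examined; leaving out the doubted libraries (E10.5 CD45- cKit- library 2, which held CD45+ transcripts, and the MBC libraries) was chosen after. For the changes below the cause was not tested, except where a setting only raises the bar (a log2 change of at least 1) or removes groups or genes from the fit. With a log2 change of at least 1 the counts were 889 (cKit), 1363 (CD45), 1262 (HSPC against CD45-), 147 (HSPC against CD45+ PS34), 674 and 779 (stage in CD45- and CD45+ gates). With only the groups compared they were 3856 (HSPC against CD45-), 71 (HSPC against CD45+ PS34) and 868 (stage, CD45+ gates). With no filter they were 182 and 162 (change of the cKit and HSPC contrasts with stage) and 67 (Ter119+), without the trend 49 and 158 (change of the cKit and CD45 contrasts with stage) and 277 (Ter119+), and with a pseudocount of 0.1 253 (Ter119+). Without the doubted libraries they were 130 (HSPC) and 349 (CD45- against CD45+ gates) for the change with stage. With an estimated correlation 16 list tests of the 8 comparisons passed in place of 58. With a replicate block 57 passed, and the megakaryocyte list in MBC was lost (adjusted p = 0.0664). For the change of the cKit contrast with stage, that block ended the list calls of stress (adjusted p = 0.0567), trophoblast (0.0708) and stem cell regulators (0.0615). For the CD45 contrast it ended that of arterial genes (0.054). The cell-cycle list gained a call for CD45- against CD45+ gates (0.0361). Replicate numbers do not pair the libraries: deviations of equally numbered libraries correlated at -0.098 to 0.071 and 7 of 17 libraries lay closest to their own number. With the replicate block 45 genes changed with stage in the cKit contrast. Leaving out single libraries gave 827 to 1855 (cKit), 1566 to 2724 (CD45), 1458 to 2297 (HSPC against CD45-), 93 to 468 (HSPC against CD45+ PS34), 737 to 1756 and 734 to 1630 (stage), 4274 to 5293 (MBC), 124 to 913 (Ter119+), and for the change with stage 4 to 247 (cKit), 35 to 348 (CD45), 21 to 126 (HSPC) and 74 to 351 (CD45- against CD45+). MBC has no value without either of its libraries. Over the 58 called lists no direction changed under another scaling or without a library, and calls were lost in 3 of 116 and 29 of 1035 values.

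In single cells, counting any value above 0 gave Prom1 72.9% (E10.5), Ly6a 100% (E10.5) and 66.7% (HSPC), Cd34 100% (E10.5) and 97.9% (HSPC), Kit 97.9% (E12.5) and 93.8% (HSPC), and Ptprc 37.5% (E12.5) and 100% (HSPC). Counting from 5 FPKM gave Prom1 0% (HSPC), Ly6a 77.1% (E12.5) and 20.8% (HSPC), and Kit 60.4%, 64.6% and 52.1% (E10.5, E12.5, HSPC). The unknown read depth limits what a value of 0 can show.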

Other observations

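The gene groups here were put together after values were seen, so they are descriptions, not tests.

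The CD45- cKit- libraries held secreted products of glandular epithelium at high levels. Prap1 was at 4061 to 19360 FPKM over the 5 libraries, Lcn2 (lipocalin 2) at 719.6 to 2035, Sprr2f at 540.9 to 2117, Guca2b at 250.9 to 1134 and Ltf (lactoferrin) at 55.08 to 283.5. Single cells of the CD45- PS34 gates did not show them: Prap1 was at 1 FPKM or more in 0 of 48 cells at E10.5 and 2 of 48 at E12.5, Guca2b and Klk1 in 0 of 48 at both, and Lcn2 in 6 and 1 of 48. A count of 0 of 48 allows a share of up to 6.25%. The single cells include cKit+ and cKit- cells, which the labels do not separate.

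Granzymes in the MBC gate differed between its 2 libraries. At E10.5 Gzmc was at 1931 FPKM, Gzmd at 1378, Gzmf at 1169 and Prf1 at 831.1, and at E12.5 they were at 148.9, 248.2, 249 and 262.2. With 1 library a stage this difference cannot be tested. E12.5 CD45+ PS34 library 1 also held Prf1 at 1370 FPKM, against 3.411 in library 2. Imprinted genes higher at E12.5 also included Meg3 (by 4.07 in the CD45- and 4.64 in the CD45+ gates), Rtl1 (3.13 and 3.33), Ndn (2.85 and 2.72) and Cdkn1c (2.67 and 2.65), while Grb10 was not called in either (-0.14 and -0.46). In single cells Igf2 was at 1 FPKM or more in 10 of 48 cells at E10.5 and 37 of 48 at E12.5, and Meg3 in 6 and 33 of 48. Among E12.5 HSPC (no E10.5 cells to compare with), Igf2 was in 6, Meg3 in 0, H19 in 17 and Cdkn1c in 27 of 48.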
